A study of Mus musculus with 12 samples.

How the data were processed

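ATAC-seq libraries of mouse embryonic fibroblasts (MEF), Stage 1 cells, Stage 2 cells and induced pluripotent stem cells (iPSC) were analysed from the deposited processed files, 3 libraries per group. The authors deposited, for each library, a read count for every region of a common set, with the number of reads outside the regions and of ambiguous reads, and an interval list for each stage. Per the submitters' processing notes, Bowtie2 2.2.6, Picard 2.6.0, SAMtools 0.1.19, HTSeq 0.5.4p3, DESeq2 1.12.4 and the build mm10 were used, without a role or order. The peak caller, the treatment of duplicate reads and any shift of read ends were not given in the sources used here. Checked on the deposited lists, the 115000 counted regions were identical to the 4 stage lists merged, each stage list held only intervals found in all 3 replicates, and all interval ends were multiples of 50 bp. The lists carry no score.

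Groups and replicate numbers were taken from the labels. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Each pair of replicates differed by more than sampling noise, with a chi-square of counts beyond that of the pair's pooled reads split at random (p at most 0.002 in 1000 splits), so no library was left out or merged. Some pairs were closer than the others of their group: the chi-square per degree of freedom was 1.02 for Stage 1 replicates 2 and 3, near the 1.00 of random splits, against 1.24 and 1.23 for the other Stage 1 pairs, and 1.19 for MEF replicates 2 and 3 against 2.08 and 2.13. It was from 1.03 to 1.20 in Stage 2 and from 1.05 to 1.10 in iPSC. Reads in no region or in several regions stayed out of library sizes and tests, except in whole-library scaling, where all reads made up the library size. The ambiguous share was between 0.0311% and 0.230% of a library. Depth per library is given with the results. Intervals and floors cover counting error only.

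Counts per region were tested with edgeR 4.0.16 (R 4.3.3) by robust quasi-likelihood F tests, which are two-sided, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and 1 model of the 4 groups; Benjamini-Hochberg adjusted p under 0.05 was called. This left 71069 regions. For genes, counts were summed over the regions that overlap a gene's span or lie within 10 kb of either end, with the coordinates of protein-coding genes of the GRCm38.p6 assembly, which is mm10 (GenomicRanges 1.54.1). Of the regions 66.2% had a gene, 14836 had more than 1, 18088 of 21887 genes had a region, and 17540 genes were tested. A gene value therefore stands for accessibility near the gene and not for its expression. The gene table gives no strand, so a planned restriction to 1 kb around a start site became 1 kb around either end of the gene. Counts of regions given beside a fold were summed over the 3 libraries of a group, and a group at 0 was set to a floor of 3 counts over the group. These counts were not set against the expected background, so the folds describe reads counted and not the cause of a low count.

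The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 17 lists with 410 members cover the pluripotency network, primed and epiblast genes, mesenchymal and fibroblast genes, epithelial genes, AP-1 and other somatic transcription factors, TGF-beta pathway genes, Wnt target genes, germline genes, primitive endoderm, trophectoderm, neural ectoderm, mesoderm and definitive endoderm genes. They also cover markers of blood cells, endothelium, skeletal muscle and neural crest. Lists were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01), two-sided, with adjustment over the 17 lists of a comparison, and again with an estimated correlation. Named genes were, per comparison, the 2 members of each list with the largest fold change in size among those past the threshold and without overlap between the libraries, and 14 genes in every comparison (Pou5f1, Sox2, Klf4, Myc, Nanog, Esrrb, Zfp42, Dppa3, Cdh1, Epcam, Thy1, Twist2, Col1a1 and Fosl1). A gene that this rule picked is not reported here. Named regions came from the 3 largest rises and 3 largest falls under the same conditions with a mean of at least 2 log2 CPM.

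Regions higher or lower than at both end points were those called in both tests, and their number was set beside that of independent lists and of simulated libraries without effects. The position of a library between MEF and iPSC was the median, over regions with an adjusted p under 0.05 and a log2 fold change of at least 2 in size, of a share of distance. This share was the distance from the MEF mean over the distance between the MEF and iPSC means (log2 CPM, prior count 2). Values per library were compared by two-sided exact permutation tests. Background was the read density of the library outside the regions over the uncounted part of the genome, which takes it to be even. For some genes this estimate lay above the observed value, such as Plac1 with 14.1 CPM in iPSC where 39.4 CPM were expected. The median over all genes in iPSC was 2.49-fold over it. Values relative to background are therefore approximate. Overlaps of interval lists were made with bedtools 2.31.1, and plots with matplotlib 3.10.9 in Python 3.11.15.

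The tests were checked on simulated data with 200 changed features, drawn from the means and library sizes of the real libraries. Each fit used only the libraries compared. The real comparisons with MEF called far more features, which makes the unadjusted p needed for a call less strict. The recoveries below therefore do not describe those comparisons. Among regions, simulated 4-fold changes were recovered in 75.8% for Stage 1 against MEF (44034 regions tested), 77.3% for Stage 2 against Stage 1 (40323), 77.3% for iPSC against Stage 2 (40226) and 80.3% for iPSC against MEF (43445). In the same order 2-fold changes were recovered in 43.3%, 31.3%, 38.8% and 44.8%. Among genes, 2-fold changes were recovered in 89.6% (16605 genes), 85.1% (16875), 85.1% (16868) and 92.5% (16558), and 1.5-fold changes in 67.2%, 61.2%, 40.3% and 55.2%. Unchanged features made up 6 of 89, 7 of 81, 4 of 87 and 6 of 91 calls of regions and 12 of 182, 12 of 174, 9 of 154 and 15 of 180 calls of genes. A simulated shift of 1 list was called, and no other list was; an earlier draw, with the genes in another order, had also called 1 unshifted list.

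Alternatives fixed before the data were examined were edgeR's RLE factors, library size only, cyclic loess with limma-trend, DESeq2 1.42.0, no filter, only the groups compared, the replicate number as a block, each library left out, a log2 fold change of at least 1, other prior counts and other overlaps. Whole-library scaling, equal depth (each library thinned to the in-region count of the shallowest one), regions near gene ends, 1 gene per region, background subtraction and a set of libraries with similar shares of reads in regions were chosen after seeing the data. So were Fisher's exact tests across regions, including those of lists among regions called higher than in MEF. No genome sequence was used here, so planned shares of regions with transcription factor motifs were not made.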

Results

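Chromatin accessibility was measured by ATAC-seq, an assay in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse embryonic fibroblasts (MEF) and at 3 later points of their conversion to induced pluripotent stem cells (iPSC). The labels call the protocol 3c enhanced reprogramming; what 3c stands for was not given in the sources used here. Stage 1 cells were taken at day 6 and Stage 2 cells after 4 further days, and the last group was established iPSC. Cells of the last 3 groups were sorted for a green fluorescent reporter of Oct4, the product of Pou5f1, and MEF were not sorted. Each group had 3 libraries, 12 in all, from a mixed C57BL/6 and 129 background. The comparisons asked how far the chromatin of sorted cells had moved from MEF by each stage, what still differed between Stage 2 cells and iPSC, and what opened or closed only in between.

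The libraries held between 14310290 reads (Stage 1 replicate 2) and 32229388 reads (MEF replicate 2). Means were 28847577 ± 3180359 reads in MEF, 16481449 ± 2281837 in Stage 1, 26073784 ± 912481 in Stage 2 and 24421422 ± 1635688 in iPSC (SD, n = 3 each). Far fewer reads fell in the 115000 regions that were counted, from 1034936 in iPSC replicate 3 to 6261903 in MEF replicate 1. The share of reads in regions was 16.7% ± 5.37 in MEF, 7.64% ± 0.415 in Stage 1, 6.03% ± 0.813 in Stage 2 and 4.94% ± 0.395 in iPSC (SD, n = 3 each). No library of one group overlapped a library of another. A two-sided exact permutation test gave p = 0.1 for each pair of groups, the smallest that 3 libraries against 3 allow. From the read density outside the regions, background reads were expected to make up 13.8% ± 5.54 of the reads inside them in MEF, 30.6% ± 1.75 in Stage 1, 39.9% ± 5.56 in Stage 2 and 48.9% ± 4.28 in iPSC (SD, n = 3 each). The estimate exceeded the observed reads of some genes, so these shares may be too high. Reads outside the regions were deposited as a total per library. Whether they were evenly spread, or differed in kind between the groups, was not tested.

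**Figure D1:**
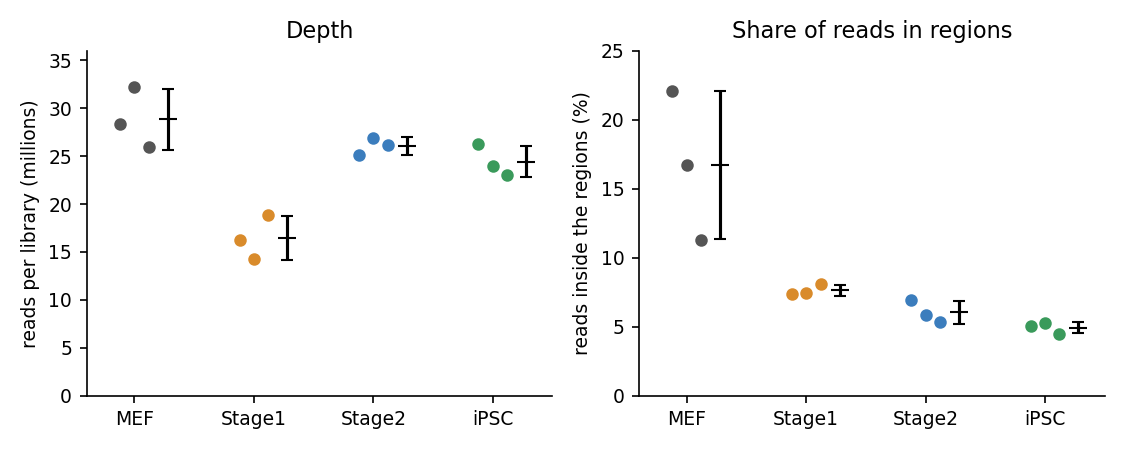
Reads per library (left; axis label gives the scale) and percent of reads inside the counted regions (right) for the 12 libraries; points are libraries, and the black marks are the group mean with its SD (n = 3). The share in regions lay between 11.3% and 22.1% in MEF and below 8.12% in every later library.

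The deposited interval lists held 86168 intervals for MEF, 36719 for Stage 1, 37485 for Stage 2 and 28590 for iPSC. Merged, the lists gave the 115000 counted regions, which cover 67212950 bp (2.47% of the mm10 genome) with a median width of 550 bp. Regions found in the MEF list alone made up 56.3% of them (64720), regions in all 4 lists 11.02% (12677), and regions shared by Stage 1, Stage 2 and iPSC but absent from the MEF list 5.87% (6746). Of the iPSC intervals, 82.7% overlapped a Stage 2 interval by at least 1 bp, 74.0% a Stage 1 interval and 51.9% a MEF interval. Each list stands for a whole stage, so these shares have no replicate error. The lists also come from libraries of unlike depth and share of reads in regions, and hold only intervals found in all 3 replicates. Absence from a list therefore does not show closed chromatin. How far these differences set the numbers of intervals was not tested.

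Across the regions, log2 accessibility of the MEF libraries was nearly unrelated to that of the later libraries (Pearson r across regions from -0.0561 to 0.111), whereas pairs of later libraries from different stages gave r from 0.699 to 0.834. Within a stage r ran from 0.957 to 0.973 in MEF, 0.846 to 0.875 in Stage 1, 0.870 to 0.890 in Stage 2 and 0.805 to 0.839 in iPSC. Regions are not independent replicates, so these values describe the libraries only. The tested regions come from merged stage lists, which leave out sites closed in every stage, so r does not stand for the whole genome.

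Gene values below are counts scaled to library size (CPM), summed over the regions linked to a gene, and every fold change is relative to the reads inside regions. Scaling to all reads of a library instead, inside and outside the regions, shifted the median log2 fold change of all genes by -0.95 for Stage 1 against MEF, -0.39 for Stage 2 against Stage 1, -0.36 for iPSC against Stage 2 and -1.69 for iPSC against MEF. The changes reported are relative to these shifts. With this scaling the median of 9, 16, 11 and 12 of the 17 lists had the other sign in these comparisons, in the same order, and the values are given with each comparison.

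By day 6 the pluripotency genes of the sorted cells had gained accessibility over unsorted MEF almost as a block. Of the 34 measured genes of the pluripotency network, 30 rose (30 adjusted over the list alone), with a median log2 fold change of 1.93, or 0.98 with whole-library scaling. The growth factor gene Fgf4 went from 4.98 ± 1.84 to 108 ± 1.93 CPM, the nuclear receptor gene Nr0b1 from 1.48 ± 1.16 to 21.7 ± 2.17 CPM. Zfp42, which encodes Rex1, went from 2.88 ± 2.37 to 36.4 ± 7.87 CPM (SD, n = 3 each). Their log2 fold changes were 4.46 ± 0.16, 4.11 ± 0.33 and 3.90 ± 0.28 (SE; edgeR adjusted p = 1.18e-36, 1.29e-18 and 2.56e-18). The core factors had smaller log2 fold changes, of 1.04 ± 0.12 for Pou5f1, 1.58 ± 0.17 for Sox2, 1.56 ± 0.11 for Nanog and 1.69 ± 0.10 for Esrrb (SE, edgeR adjusted p at most 2.59e-12). In the same order, their linked regions already had 43.8, 15.1, 50.7 and 67.2 CPM in MEF. Background alone would give them 6.77, 4.33, 6.45 and 23.4 CPM there. The smaller folds start from this level, and the part of regions shared with other genes was not tested. Dppa3, a germ cell and naive pluripotency marker, rose by 2.49 ± 0.15. The reprogramming factor genes Klf4 and Myc did not pass the test, at 0.07 (adjusted p = 0.628) and 0.05 (adjusted p = 0.688) on the log2 scale, and had values of -0.87 and -0.91 with whole-library scaling.

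Epithelial genes rose and mesenchymal genes fell over the same interval. Among 32 epithelial genes 22 rose and 3 fell (22 and 4 adjusted over the list alone; median 1.07, or 0.14 with whole-library scaling). They included the tight junction gene Cldn7 (3.87 ± 0.44), the adhesion gene Epcam (2.89 ± 0.28) and Cdh1, which encodes E-cadherin (1.55 ± 0.12). Among 47 mesenchymal and fibroblast genes 38 fell and 1 rose (38 and 1 adjusted over the list alone; median -0.95). The transcription factor gene Twist2 dropped from 104 ± 6.44 to 13.6 ± 1.70 CPM, the fibroblast surface marker Thy1 from 55.9 ± 2.98 to 13.6 ± 3.28 CPM (SD, n = 3 each). The matrix genes Bgn and Col1a1 dropped from 25.9 ± 4.15 to 3.77 ± 2.05 CPM and from 121 ± 6.33 to 57.3 ± 4.23 CPM (SD, n = 3 each). Background reads alone would give the regions of Twist2 16.2 CPM and those of Thy1 12.9 CPM in Stage 1, so both genes ended near background.

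The TGF-beta pathway and the somatic transcription factors lost accessibility as well. Of 25 TGF-beta pathway genes 19 fell and 1 rose (19 and 1 adjusted over the list alone; median -0.77), including Tgfbi at -2.48 ± 0.17 (log2, SE). Of 30 AP-1 and other somatic factors 17 fell and 4 rose (17 and 4 adjusted over the list alone; median -0.32). They included Smad3 at -1.83 ± 0.11 and Batf at -1.76 ± 0.24. Fosl1 did not pass at -0.25 (adjusted p = 0.0738; -0.34 and past the threshold at 0.0168 without MEF replicate 1). These 4 lists and the pluripotency list passed camera, a test of a list against all other genes, with adjusted p between 1.95e-18 (pluripotency) and 0.00218 (AP-1), and did so with an estimated correlation too (adjusted p at most 0.0271).

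**Figure D2:**
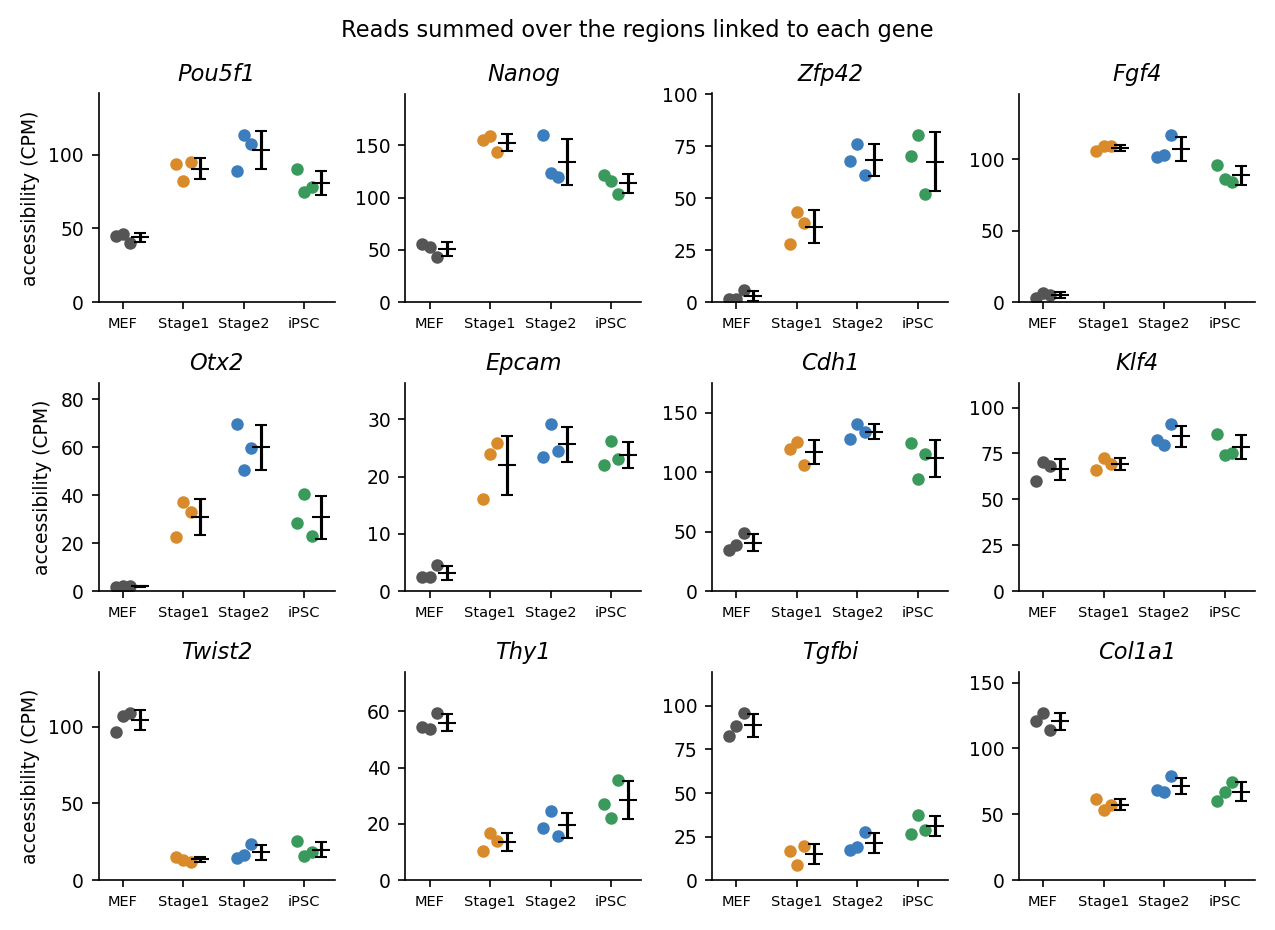
Accessibility in CPM summed over the regions linked to 12 genes in the 12 libraries; points are libraries, and the black marks are the group mean with its SD (n = 3). Pluripotency, primed and epithelial genes such as Fgf4, Zfp42, Otx2 and Epcam were low in MEF and higher in all later libraries, Twist2, Thy1, Tgfbi and Col1a1 the reverse, and Klf4 differed little.

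Genes of the primed epiblast and of several lineages that neither MEF nor iPSC represent also rose relative to the reads in regions. Of 19 primed and epiblast genes 11 rose and 4 fell (12 and 5 adjusted over the list alone; median 0.76), with Otx2 at 3.87 ± 0.27 and Foxd3 at 2.52 ± 0.17 (log2, SE). Rises outnumbered falls among 18 definitive endoderm genes (12 and 2; Sox17 3.55, Foxa2 2.54) and 18 trophectoderm genes (12 and 4; Tfap2c 2.30, but Plac1 -3.07). They also did among 26 neural ectoderm genes (14 and 5; En2 3.16, Sox1 2.17), 21 germline genes (10 rose; Tex19.1 4.22, Zscan4d 3.76) and 18 macrophage and blood genes (9 and 3; Cd48 2.80, Ikzf1 2.75). The counts adjusted over the list alone were equal except for 10 rises among blood genes. All 6 lists passed camera (adjusted p from 0.00181 to 0.0413) and lost the call with an estimated correlation, where adjusted p was 0.0930 for primed, 0.121 for definitive endoderm, 0.0683 for trophectoderm, 0.167 for neural, 0.243 for germline and 0.0930 for blood genes. The germline list also lost it without MEF replicate 1 (adjusted p = 0.0580) or Stage 1 replicate 3 (0.0623), and the blood list without MEF replicate 1 (0.0635) or Stage 1 replicate 3 (0.0616). With whole-library scaling their medians were -0.18 for primed, 0.06 for definitive endoderm, -0.14 for trophectoderm, -0.33 for neural, -0.37 for germline and -0.33 for blood genes.

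The remaining lists did not pass camera in this comparison. Rises and falls numbered 11 and 6 of 22 Wnt target genes (T, the mesoderm factor Brachyury, 3.94; Evx1 2.19), 7 and 9 of 19 primitive endoderm genes (Ttr 3.72) and 7 and 4 of 21 mesoderm genes (Tbx20 2.15). They numbered 4 and 7 of 16 endothelial genes (Emcn -3.07, Tie1 -2.68), 5 and 2 of 12 muscle genes (Acta1 -2.11, Pax7 1.80) and 5 and 1 of 9 neural crest genes (Tfap2b 3.34), with the same counts adjusted over the list alone. With whole-library scaling the positive medians of the Wnt, mesoderm, muscle and neural crest lists became -0.75, -0.84, -0.68 and -0.48. The primitive endoderm list had a median of -0.42 but a mean of 0.21.

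In all, 28456 regions were more open and 28700 less open in Stage 1 than in MEF, 80.4% of the 71069 tested (edgeR quasi-likelihood test, adjusted p under 0.05), and 5686 genes rose and 5733 fell of 17540. With each library thinned to the same number of reads in regions, 22829 regions were more open and 16187 less open. Of the genes that rose, 5606 stood above 2 times the background level in Stage 1. Whole-library scaling left 1326 rises and gave 12233 falls among genes, and the share of rises among called regions was 37.4% against 49.8%. Among regions with the largest changes, one that overlaps the collagen gene Col24a1 (mm10, chromosome 3, 145443051 to 145443850) had 140 reads in Stage 1 and 1 in MEF, a ratio of 404 (95% interval 71.3 to 16069, counting error only). A region near Skint9 (chromosome 4, 112378751 to 112379300) had 47 reads in Stage 1 and none in MEF, at least 45.2-fold higher at a floor of 3 counts over the group. On the falling side, a region linked to Spata4 (chromosome 8, 54609201 to 54609800) had 189 reads in MEF and none in Stage 1, at least 21.8-fold lower. One linked to Opcml (chromosome 9, 27813001 to 27813950) had 424 and 1, a ratio of 147 (26.2 to 5817).

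**Figure D3:**
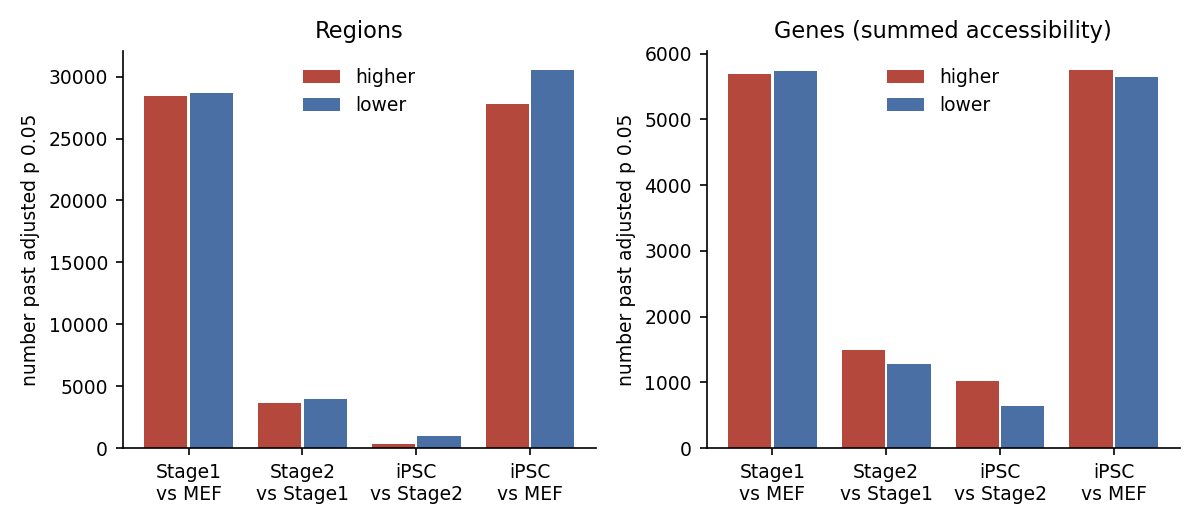
Number of regions (left) and genes (right) past an adjusted p of 0.05 in edgeR for the 4 comparisons, more open in the group named first (red) or less open (blue). Both comparisons with MEF call at least 57156 regions, and iPSC against Stage 2 calls 354 higher and 964 lower.

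Between Stage 1 and Stage 2, 2781 genes changed, against 11419 between MEF and Stage 1. Of the 17 lists the pluripotency, primed and neural lists rose relative to other genes by camera (adjusted p = 0.00136, 0.000185 and 0.00136), and none did with an estimated correlation, where each had an adjusted p = 0.204. With whole-library scaling the median of every list except the neural one turned from positive to negative, with values from -0.37 (germline) to -0.06 (primed). In the pluripotency network 9 of 34 genes rose and 2 fell (10 and 3 adjusted over the list alone; median 0.19, or -0.18 with whole-library scaling). Dppa4 rose from 17.01 ± 3.32 to 42.2 ± 14.3 CPM, Dppa5a from 72.6 ± 6.87 to 148 ± 6.47 CPM (SD, n = 3 each). Zfp42 rose from 36.4 ± 7.87 to 68.4 ± 7.57 CPM, Esrrb from 214 ± 19.5 to 296 ± 10.8 CPM and Sox2 from 44.3 ± 8.97 to 64.4 ± 8.84 CPM (SD, n = 3 each). Of 19 primed and epiblast genes 8 rose (9 rises and 1 fall adjusted over the list alone; median 0.34, or -0.06 with whole-library scaling), led by Sox3 at 2.19 ± 0.48 and Otx2 at 0.96 ± 0.18 (log2, SE). Of 26 neural ectoderm genes 6 rose (6 adjusted over the list alone; median 0.39, or 0.01), including Olig1 at 1.28 ± 0.33 and Pax3 at 0.66 ± 0.21 (log2, SE). Pou5f1, Nanog, Dppa3, Klf4, Myc, Cdh1, Epcam, Thy1, Twist2, Col1a1 and Fosl1 did not pass the test, with log2 values between -0.27 (Dppa3) and 0.54 (Thy1). The positive values of Pou5f1, Klf4, Myc, Cdh1, Epcam and Col1a1 became -0.22, -0.11, -0.12, -0.19, -0.17 and -0.08 with whole-library scaling. Sox2 and Pax3 lost the call without Stage 1 replicate 3 (adjusted p = 0.203 and 0.0898) and without Stage 2 replicate 1 or 3, and Pax3 also without Stage 1 replicate 1.

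Other genes that changed between these stages included signalling genes. The Wnt feedback gene Axin2 fell from 127 ± 22.9 to 71.2 ± 3.98 CPM and the Wnt effector Lef1 rose from 77.0 ± 14.7 to 131 ± 9.51 CPM (SD, n = 3 each). Of 22 Wnt target genes 4 rose and 1 fell (5 and 1 adjusted over the list alone). Among 25 TGF-beta pathway genes 4 rose and 3 fell (5 and 3), with Bmp4 at 0.60 ± 0.18 and Smad4 at -0.65 ± 0.13 (log2, SE). Among 47 mesenchymal genes 9 rose and 4 fell (10 and 6), with Twist1 at 1.06 ± 0.22 and Prrx2 at 1.05 ± 0.25. Rises and falls numbered 1 and 1 of 32 epithelial genes, 2 and 1 of 30 AP-1 factors, 2 and 1 of 18 trophectoderm genes, 2 and 1 of 21 mesoderm genes and 4 and 1 of 18 definitive endoderm genes. Rises numbered 3 germline, 4 primitive endoderm, 1 blood and 4 endothelial genes. Adjusted over the list alone, the counts differed for mesoderm genes (3 and 1), epithelial genes (the 1 rise) and AP-1 factors (neither). Among the genes that passed were Elf3 (0.73) and Tjp3 (-0.30) of the epithelial, Egr3 (0.47) of the AP-1 and Rpl10l (1.13) and Sycp1 (0.84) of the germline list. Others were Gata4 (0.58) and Sox17 (0.51) of the primitive endoderm, Krt7 (0.91) and Fgfr2 (-0.51) of the trophectoderm and Kdr (0.66) of the mesoderm list. The same held for Prox1 (-0.81) and Foxa1 (0.68) of the definitive endoderm, Ptprc (0.63) of the blood and Fli1 (1.01) and Cldn5 (0.84) of the endothelial list. No muscle or neural crest gene passed in edgeR, where 2 muscle genes had an unadjusted p under 0.05, or in DESeq2. Some of these risers stood near background in Stage 2. Kdr had 25.7 and 41.6 CPM in Stage 1 and Stage 2 where 25.4 and 34.2 CPM were expected from it, Krt7 9.94 and 18.7 CPM against 9.58 and 12.9 CPM, and Prrx2 14.2 and 29.3 CPM against 14.2 and 19.04 CPM. Above 2 times the background level in Stage 2 stood 5 of 9 mesenchymal, 3 of 4 TGF-beta, 1 of 2 AP-1, 2 of 3 germline, 3 of 4 primitive endoderm, 1 of 2 trophectoderm, 1 of 2 mesoderm, 3 of 4 endothelial and 5 of 6 neural risers, and all risers of the other lists. Several of these calls were lost with a library left out, which leaves its group with fewer libraries and the test with less power. The highest adjusted p was 0.203 for Egr3 without Stage 1 replicate 2, 0.198 for Tjp3, 0.165 for Krt7, 0.161 for Sox17 and 0.111 for Bmp4 without Stage 1 replicate 1. It was 0.159 for Sycp1 without Stage 2 replicate 3, 0.0866 for Kdr without Stage 1 replicate 2, 0.0857 for Ptprc without Stage 1 replicate 1, and 0.0830 for Prrx2 and 0.0656 for Cldn5 without Stage 1 replicate 3.

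Over all regions 3653 opened further and 3997 closed, 10.8% of those tested, and 1497 genes rose and 1284 fell. Of the genes that rose, 1255 stood above 2 times the background level in Stage 2. Regions that closed lay within 1 kb of a gene end in 25.1% of cases and regions that opened in 9.20%, against 20.6% of all tested regions. The odds ratio of closed to opened was 3.30 (95% interval 2.89 to 3.78, Fisher's exact test across regions, which are not replicates). The largest changes included a region without a linked gene on chromosome 4 (73517351 to 73518000), 15.9-fold higher in Stage 2 (7.53 to 40.3), and another on chromosome 3 (106252101 to 106252950), 8.51-fold lower (6.18 to 11.96). Counts of regions and genes changed with a library left out, which leaves its group with fewer libraries and the test with less power. Without Stage 1 replicate 3 there were 1890 rises and 2147 falls of regions and 810 and 824 of genes. Rises of regions numbered 2324 without Stage 1 replicate 2, 2412 without Stage 2 replicate 1 and 2408 without Stage 2 replicate 2, and falls 2428 and 2403 without Stage 2 replicate 2 or 3. Rises of genes numbered 944 without Stage 1 replicate 2, 919 without Stage 2 replicate 2 and 915 without Stage 2 replicate 3. DESeq2, which covered 114998 regions where edgeR tested 71069, called 1569 rises and 1774 falls of regions. Whole-library scaling left 1100 rises of regions and 62 of genes.

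Between iPSC and Stage 2 cells edgeR called 1.85% of the tested regions. An unadjusted p under 0.05 was found for 10860 of 71069 regions, so the share called is not the extent of the difference. Relative to other genes the pluripotency list fell and the mesenchymal list rose by camera (adjusted p = 1.14e-06 and 6.39e-05), and neither passed with an estimated correlation (adjusted p = 0.0686 for both). With whole-library scaling the medians of all 17 lists were negative, from -0.62 (pluripotency) to -0.08 (germline). Of 34 pluripotency genes 6 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.26), with Tbx3 going from 74.5 ± 2.51 to 51.9 ± 7.55 CPM and Mybl2 from 229 ± 5.52 to 171 ± 15.4 CPM. Of 19 primed and epiblast genes 5 fell and 1 rose (5 and 2 adjusted over the list alone; median -0.14). Otx2 went from 60.0 ± 9.48 to 30.8 ± 8.89 CPM, close to its Stage 1 level, and Zic2 from 161 ± 14.9 to 100.01 ± 6.89 CPM (SD, n = 3 each). Of 47 mesenchymal genes 10 rose (14 adjusted over the list alone; median 0.26, or -0.10 with whole-library scaling), including the homeobox genes Meox2 (1.03 ± 0.28) and Prrx1 (0.67 ± 0.16, log2, SE). Meox2 lost the call without Stage 2 replicate 2 or 3 or iPSC replicate 1 or 3 (adjusted p up to 0.0761), Prrx1 without Stage 2 replicate 2 (0.0840) and Tbx3 without iPSC replicate 1 (0.104). None of Pou5f1, Sox2, Klf4, Myc, Nanog, Esrrb, Zfp42, Dppa3, Cdh1, Epcam, Thy1, Twist2, Col1a1 and Fosl1 passed the test, with log2 values between -0.39 (Sox2) and 0.51 (Thy1); Pou5f1, at -0.34, passed only without Stage 2 replicate 1 (-0.44, adjusted p = 0.0401). The positive values of Myc and Twist2 became -0.15 and -0.18 with whole-library scaling.

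The background share rose between these 2 groups as well, and the median accessibility of the mesenchymal list over the level expected from background was 1.63-fold in both. It was 5.35-fold in Stage 2 and 3.56-fold in iPSC for the pluripotency list and 3.25-fold and 2.49-fold for all genes. Of the 10 mesenchymal genes that rose, 2 stood above 2 times the background level in iPSC. Prrx1, at 41.3 CPM in Stage 2 and 64.8 CPM in iPSC, had an expected background of 40.9 and 52.7 CPM. The primitive endoderm (adjusted p = 0.00619), primed (0.00872), epithelial (0.0327) and germline lists (0.0423) passed camera as well. With an estimated correlation none did, with adjusted p = 0.193 for primed and primitive endoderm, 0.251 for epithelial and 0.313 for germline genes. The whole-library medians of the germline and primitive endoderm lists were -0.08 and -0.10, against 0.28 and 0.25. Cyclic loess turned the medians of the trophectoderm, muscle and neural crest lists, which did not pass camera, to -0.01, -0.05 and -0.07. The epithelial list lost the call without Stage 2 replicate 3 (adjusted p = 0.102) or iPSC replicate 2 (0.0764), and the germline list without Stage 2 replicate 1 (0.0628), iPSC replicate 1 (0.0554) or iPSC replicate 2 (0.0602).

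Single genes of other pathways changed too. Axin2 rose again, from 71.2 ± 3.98 to 105 ± 2.55 CPM, the TGF-beta receptor gene Tgfbr2 rose from 26.4 ± 2.97 to 45.9 ± 11.8 CPM, and the BMP target Id3 fell from 77.7 ± 10.1 to 46.7 ± 2.00 CPM (SD, n = 3 each). Background alone would give the regions of Tgfbr2 28.8 CPM in Stage 2 and 37.2 CPM in iPSC, and none of the 3 TGF-beta genes that rose stood above 2 times the background level in iPSC. Rises and falls numbered 4 and 3 of 22 Wnt target genes (6 and 3 adjusted over the list alone; Evx1 -0.64) and 3 and 1 of 25 TGF-beta genes (5 and 1). They numbered 3 and 2 of 30 AP-1 and somatic factors (3 and 4; Nfia 0.46, Srf -0.60). They numbered 2 and 1 of 21 mesoderm genes (4 and 1; Actc1 1.02, Tbx6 -0.48), 1 and 2 of 18 blood genes (Tal1 0.55, Cd68 -0.53) and 1 and 1 of 12 muscle genes (Chrna1 0.55, Mylpf -0.36). In the germline list 2 of 21 rose (3 adjusted over the list alone), the meiotic genes Sycp1 (0.79) and Sycp3 (0.66), and in the primitive endoderm list 3 of 19 (6 adjusted over the list alone), among them Col4a1 (0.45) and Col4a2 (0.42). Both stood at background, Col4a1 with 70.4 and 95.1 CPM in Stage 2 and iPSC where 68.9 and 88.8 CPM were expected from it, and Col4a2 with 78.2 and 104 CPM against 84.5 and 109 CPM. None of the 3 AP-1 risers and not the epithelial one stood above 2 times the background level in iPSC, and 1 of the 3 primitive endoderm risers did. A single gene rose in each of the epithelial (Krt19 0.83), trophectoderm (Fgfr2 0.70), neural (Neurod1 0.53), endothelial (Pecam1 0.53) and neural crest lists (Mitf 0.47). Adjusted over the list alone, 2 rose in the trophectoderm, endothelial and neural crest lists and the epithelial and neural rises did not pass. The AP-1 and neural lists had medians of -0.02 and -0.01 but means of 0.03 and 0.03. No definitive endoderm gene passed in edgeR or DESeq2, or had an unadjusted p under 0.05 in either. Most of these single-gene calls were lost with a library left out, which leaves its group with fewer libraries and the test with less power. The highest adjusted p was 0.304 for Col4a2 and 0.224 for Col4a1 without Stage 2 replicate 1, 0.284 for Krt19 and 0.118 for Sycp3 without iPSC replicate 1. It was 0.277 for Neurod1, 0.166 for Evx1, 0.159 for Mylpf, 0.111 for Tbx6 and 0.0622 for Tgfbr2 without iPSC replicate 2. It was 0.163 for Tal1 and 0.136 for Pecam1 without Stage 2 replicate 3, 0.122 for Sycp1 and 0.0797 for Srf without Stage 2 replicate 1, 0.0687 for Actc1 without iPSC replicate 3 and 0.0635 for Chrna1 without iPSC replicate 2.

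Over all regions 354 were more open and 964 less open in iPSC than in Stage 2, and 1018 genes rose and 635 fell; 532 of the genes that rose stood above 2 times the background level in iPSC. With whole-library scaling 27 regions were higher and 609 lower, and edgeR called 39 genes lower and 0 higher (63 higher and 3564 lower at an unadjusted p under 0.05; DESeq2 with its own scaling 362). A region linked to the matrix gene Thbs2 (chromosome 17, 14662251 to 14662900) had 18 reads in iPSC and 2 in Stage 2, a ratio of 11.4 (2.72 to 101). It lost the call without Stage 2 replicate 1 or iPSC replicate 3 (adjusted p = 0.132 and 0.205). A region without a linked gene on chromosome 10 (66475701 to 66476200) was 6.13-fold lower (2.93 to 14.8). Leaving out any library, which also lowers the power of the test, lowered the counts of regions and genes called. Rises of regions numbered 62, 107 and 183 without Stage 2 replicate 1, 2 or 3 and 79, 80 and 104 without iPSC replicate 1, 2 or 3. Falls numbered 160 and 416 without Stage 2 replicate 1 or 2 and 272, 286 and 302 without iPSC replicate 1, 2 or 3. Gene rises were 500, 453 and 655 without Stage 2 replicate 1, 2 or 3 and 662, 500 and 588 without iPSC replicate 1, 2 or 3. Gene falls were 276 and 397 without Stage 2 replicate 1 or 2 and 354, 275 and 331 without iPSC replicate 1, 2 or 3. DESeq2 called 52 of its 114998 regions higher and 642 lower, and 362 genes higher and 375 lower. With only the 2 groups in the model 1350 regions were higher and 1467 lower and 1072 genes lower, and cyclic loess gave 467 regions and 965 genes lower.

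**Figure D4:**
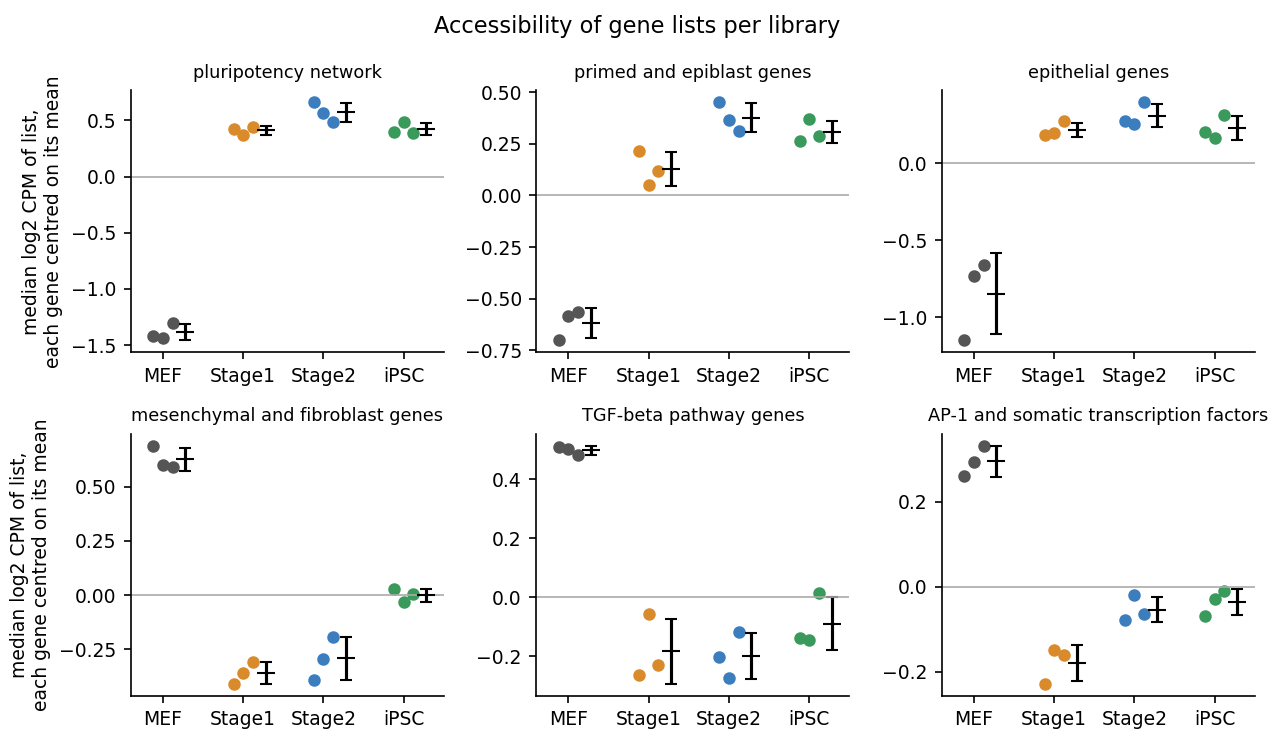
Median log2 CPM of 6 gene lists in the 12 libraries, each gene centred on its mean over libraries; points are libraries, and the black marks are the group mean with its SD (n = 3). The pluripotency, primed and epithelial lists lay lowest in MEF and the mesenchymal, TGF-beta and AP-1 lists highest, relative to the reads in regions; with whole-library scaling the primed and epithelial medians of iPSC against MEF turned to -0.61 and -0.56, and the primed median of Stage 1 against MEF to -0.18.

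From MEF to iPSC, the end points of the series, the pluripotency network rose in 31 of 34 genes and fell in 1 (32 and 1 adjusted over the list alone; median 1.89, or 0.21 with whole-library scaling). Zfp42 rose to 67.6 ± 14.3 CPM and Nr0b1 to 27.1 ± 2.24 CPM (SD, n = 3 each), log2 fold changes of 4.82 ± 0.24 and 4.41 ± 0.32 (SE; edgeR adjusted p = 4.63e-24 and 1.93e-20). Sox2 rose by 1.75 ± 0.18, Esrrb by 1.90 ± 0.10 and Dppa3 by 2.21 ± 0.16, and rises of Nanog (1.14), Pou5f1 (0.88), Cdh1 (1.49) and Myc (0.54) turned to -0.56, -0.82, -0.19 and -1.18 with whole-library scaling. Klf4 did not pass at 0.25 (adjusted p = 0.0506), and was at -1.43 with that scaling. Of 32 epithelial genes 22 rose and 4 fell (22 and 4 adjusted over the list alone; median 1.1, or -0.56 with whole-library scaling), with Epcam at 3.00, Cldn7 at 3.20 and the tight junction gene Marveld2 at 3.08. Of 47 mesenchymal genes 37 fell and 3 rose (38 and 3 adjusted over the list alone; median -0.62), with Twist2 at -2.36, Bgn at -2.67, Thy1 at -0.99 and Col1a1 at -0.86.

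The TGF-beta list fell in 20 of 25 genes and rose in 1 (21 and 1 adjusted over the list alone; median -0.69), the riser being Bmp4, at 1.57 or -0.12 with whole-library scaling. The AP-1 and somatic list fell in 18 of 30 and rose in 4 (18 and 4 adjusted over the list alone; median -0.37; Cebpa -1.42, Smad3 -1.27, Fosl1 -0.33). Fosl1 lost the call without MEF replicate 2 or 3 or iPSC replicate 1 or 2, with adjusted p up to 0.102. Lineage lists rose relative to the reads in regions by camera with the preset correlation, but with an estimated one only the trophectoderm list of these 8 did, and each had a negative median with whole-library scaling. Rises and falls were 12 and 1 of 19 primed genes (Otx2 3.88, Sox3 3.56; whole-library median -0.61), 17 and 3 of 26 neural genes (En2 3.78, Neurod1 2.78; -0.48) and 14 of 18 definitive endoderm genes (Sox17 3.95, Foxa2 2.87; -0.73). They were 15 of 21 germline genes (Tex19.1 4.15, Zscan4d 3.35; -0.66), 12 and 2 of 18 trophectoderm genes (Esx1 2.74, Plac1 -2.44; -0.82) and 14 and 3 of 22 Wnt target genes (T 4.59, Lef1 1.77; -1.21). They were 12 and 4 of 21 mesoderm genes (Isl1 1.88; -0.93) and 5 and 1 of 9 neural crest genes (Tfap2b 3.48, Foxd3 3.07; -1.30). Adjusted over the list alone only the trophectoderm count differed, with 3 falls. Background could account for part of these rises: 10 of the 12 primed, 15 of 17 neural, 9 of 14 Wnt, 11 of 12 trophectoderm, 11 of 12 mesoderm, 4 of 5 neural crest and 2 of 4 AP-1 risers rose by more CPM than the expected background did, as did 20 of 22 epithelial and all pluripotency, definitive endoderm and germline risers. Above 2 times the background level in iPSC stood 10 primed, 15 neural, 12 Wnt, 12 of 15 germline, 9 trophectoderm and 9 mesoderm risers.

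The pluripotency, mesenchymal, epithelial, AP-1, TGF-beta and trophectoderm lists passed camera with the preset correlation (adjusted p at most 0.00361) and with an estimated correlation (adjusted p at most 0.0384). The other 7 of these lists passed with the preset only. With an estimated correlation the adjusted p = 0.0502 for primed and for neural, 0.0511 for definitive endoderm, 0.0666 for germline, 0.121 for Wnt, 0.113 for mesoderm and 0.0835 for neural crest genes, whose preset call was also lost without MEF replicate 3 (adjusted p = 0.0525). Blood (11 and 3 of 18; Cd48 3.34, Ikzf1 2.76), primitive endoderm (9 and 6 of 19, or 9 and 7 adjusted over the list alone; Ttr 4.51), endothelial (6 and 5 of 16; Emcn -2.82, Cldn5 2.50) and muscle genes (5 and 2 of 12; Myf5 2.15, Pax7 2.15) did not pass. The positive medians of the blood, primitive endoderm and muscle lists became -1.09, -1.34 and -1.37 with whole-library scaling, and that of the primitive endoderm list -0.14 with cyclic loess.

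Between the end points 27787 regions were more open and 30564 less open in iPSC, 82.1% of those tested, and 5755 genes rose and 5651 fell. Of the genes that rose, 4844 rose by more than the expected background and 5030 stood above 2 times its level in iPSC. Libraries thinned to the same number of reads in regions gave 22610 rises and 17262 falls of regions; whole-library scaling gave 16839 rises of regions, and 797 rises and 15174 falls of genes. A region on the X chromosome without a linked gene (64978751 to 64979450) had 74 reads in iPSC and none in MEF, at least 70.7-fold higher at the floor of 3 counts over the group. One on chromosome 15 (90431951 to 90432850) was 46.2-fold lower (22.3 to 115). Regions that closed lay within 1 kb of a gene end in 21.6% of cases and regions that opened in 12% (odds ratio 2.01, 1.92 to 2.11, Fisher's exact test across regions), against 20.6% of all tested regions. The shares of closed and opened regions were 16.4% and 13.2% in Stage 1 against MEF, and 24.8% and 16.7% in iPSC against Stage 2.

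Some regions were called more open at a stage than at both end points. In Stage 1, 4273 regions were more open than in both MEF and iPSC, where independent lists of calls would share 2731. Simulated libraries without effects gave between 0 and 3 calls in a comparison and shared no higher region, but up to 1 lower region in a draw, more than independent lists of that size would. The excess over 2731 is therefore not taken as an effect. The values are relative to the reads in regions, of which background was expected to make up more in iPSC than in either stage, and no test of background was made on these regions. They held 25 of 180 tested regions linked to the pluripotency network (odds ratio 2.53, 95% interval 1.59 to 3.88, Fisher's exact test across regions, which are not replicates, adjusted p = 0.00167). Among regions called more open than in MEF alone, where the list had 25 of 150, no such difference was found (odds ratio 1.13, 0.705 to 1.75, adjusted p = 0.944). The first call was also lost without Stage 1 replicate 1 (adjusted p = 0.107) or iPSC replicate 2 or 3 (0.0598 and 0.0697), with library size only (0.136), cyclic loess (0.0858) and equal depth (0.0508). The 25 included 3 of 4 regions of Sall4, 2 of 4 of Nanog and 2 of 5 of Fgf4, genes picked after their values were seen. In Stage 2, 721 regions were more open than at both end points (387 from independent lists, none simulated). Primed and epiblast genes had 7 of 83 (odds ratio 9.06, 3.51 to 19.7, adjusted p = 0.000389), and 7 of 49 among regions called more open than in MEF alone (6.47, 2.45 to 14.6, adjusted p = 0.00373). The call was lost, with 2 regions left each time, without Stage 2 replicate 1 (adjusted p = 0.148) or iPSC replicate 1 or 3 (0.354 and 0.478), and the odds ratio was 17.4 without Stage 2 replicate 2 and 21.01 without iPSC replicate 2. Among the 7 were both tested regions of Otx2 and 3 of 13 of Etv5, again picked after their values were seen. The pluripotency network had 7 of 180 (odds ratio 3.98, 1.57 to 8.41, adjusted p = 0.0218), a call lost among regions more open than in MEF (1.83, 0.721 to 3.89, adjusted p = 0.502). It was also lost without any 1 library of Stage 2 or iPSC (adjusted p from 0.338 to 1), with library size only (0.684), cyclic loess (1), DESeq2 (0.527), equal depth (0.221) and whole-library scaling, where the odds ratio was 0.731. No other list was over-represented at an adjusted p under 0.05 in either test, and neural genes had 0 of 42 among regions more open in Stage 1 than in MEF (adjusted p = 0.0310).

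Regions less open than at both end points numbered 1681 in Stage 1 (1934 from independent lists, at most 1 simulated) and 121 in Stage 2 (151, at most 1), fewer than independent lists would share. Both comparisons use the same 3 libraries of the stage, which cannot be split, so part of each overlap may come from those libraries. The Stage 2 counts changed with the library left out, which leaves its group with fewer libraries. The 721 became 125 without Stage 2 replicate 1, 342 without Stage 2 replicate 2, 206, 240 and 243 without iPSC replicate 1, 2 or 3 and 1169 without MEF replicate 1. The 121 became 18, 33 and 80 without Stage 2 replicate 1, 2 or 3, 25, 33 and 25 without iPSC replicate 1, 2 or 3 and 194 without MEF replicate 1. The 1681 became 762 without Stage 1 replicate 3, 1111 without iPSC replicate 1 and 972 without iPSC replicate 3. Scaling and the test also mattered: DESeq2 gave 355 and 16 regions lower than both end points in Stage 1 and Stage 2 and whole-library scaling 250 and 4, against 7534 higher in Stage 1.

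On the scale from MEF (0) to iPSC (1), the sorted cells of both intermediate stages lay at the iPSC end over the regions gained. Over 18581 regions gained between MEF and iPSC by at least 2 on the log2 scale, the median position was 0.990 ± 0.0259 in Stage 1 and 1.05 ± 0.0327 in Stage 2 (SD, n = 3 each). Over 13751 regions lost it was 1.08 ± 0.0168 and 1.04 ± 0.0536. The measure saturates there, with a median of 1 in every Stage 1 and Stage 2 library after background subtraction, so values above 1 may come from the larger background share in iPSC and do not place the stages below iPSC. Stage 2 differed from Stage 1 by 0.0549 over gained regions (two-sided exact permutation p = 0.1, the smallest possible) and by -0.0460 over lost regions (exact p = 0.3). With whole-library scaling the means were 1.13 in both stages over gained regions, a difference of 0.00498 (exact p = 1), and 0.913 and 0.962 over lost regions, a difference of 0.0492 with the other sign (exact p = 0.1, the smallest possible). In simulated libraries placed at 0.5 the measure returned 0.474 for gained and 0.468 for lost regions.

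**Figure D5:**
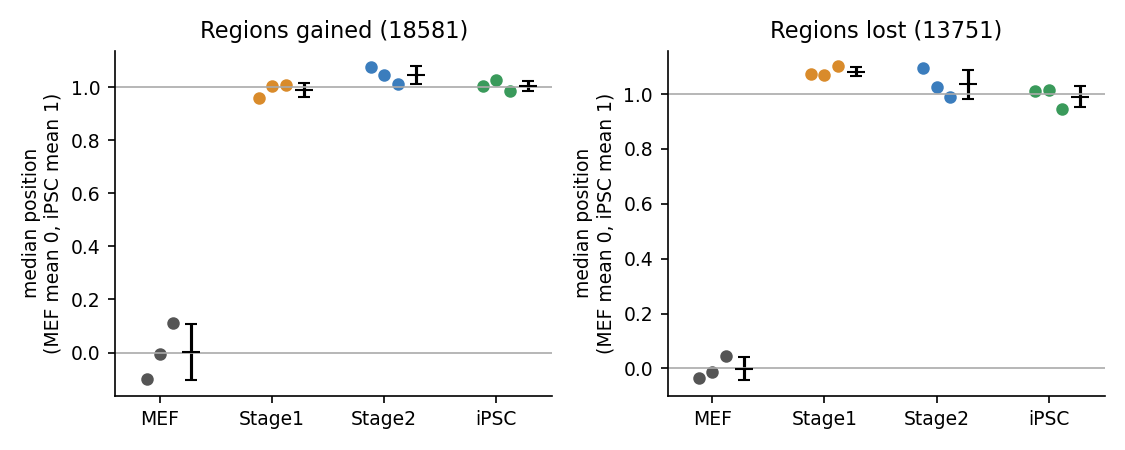
Median position of each library between the MEF mean (0) and the iPSC mean (1) over regions gained (left, 18581) and lost (right, 13751) between MEF and iPSC; points are libraries, and the black marks are the group mean with its SD (n = 3). Stage 1 and Stage 2 libraries lie between 0.960 and 1.10 in both panels.

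The X chromosome held 1.78% ± 0.0919 of the reads in regions in MEF, 2.02% ± 0.0839 in Stage 1, 2.06% ± 0.0628 in Stage 2 and 1.75% ± 0.0735 in iPSC (SD, n = 3 each). The change from Stage 2 to iPSC was -0.23 on the log2 scale, with no overlap between libraries (exact permutation p = 0.1, the smallest possible; 0.233 adjusted over the chromosomes), and no autosome moved by more than chromosome 17 (-0.07) there. From MEF to Stage 1 the X share changed by 0.18 and the shares of chromosomes 17, 15, 19 and 18 by 0.24, -0.24, -0.20 and -0.19, all with an exact permutation p = 0.1 (0.117 adjusted). Their order depended on a few regions, since without the top 1% of regions X was at 0.20 and these chromosomes at 0.14, -0.22, -0.16 and -0.18. The Y chromosome held 0.00916% ± 0.000661 in MEF, 0.0391% ± 0.00331 in Stage 1, 0.0396% ± 0.00514 in Stage 2 and 0.0295% ± 0.00456 in iPSC (SD, n = 3 each). Its log2 change was 2.09 from MEF to Stage 1 and 1.69 from MEF to iPSC (exact p = 0.1 for each), and -0.42 from Stage 2 to iPSC (exact p = 0.2). The labels give no sex of the animals.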

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

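The tests of read number, of the region set and of enrichment in this part were chosen only after the result was seen. Reads outside the counted regions were counted for no region or gene. They entered comparisons only through the library size of whole-library scaling and through the background estimate. They made up 92.3% ± 0.422 of the reads in Stage 1, 93.9% ± 0.820 in Stage 2 and 95.02% ± 0.399 in iPSC, against 83.1% ± 5.43 in MEF (SD, n = 3 each; two-sided exact permutation p = 0.1 for each against MEF, the smallest possible). This excess over the starting cells is why they are given here.

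MEF libraries held a larger share of their reads in the regions than any later library. Read number as the cause is argued against by Stage 2, whose libraries were read nearly as deeply and whose highest share was 6.91% where the lowest MEF share was 11.3%. A region set made mostly of MEF intervals is argued against as the whole cause, since over regions of all 4 stage lists the mean MEF share was still 1.70 times that of Stage 1 (2.18 times over all regions), with the lowest MEF library at 3.51% and the highest Stage 1 library at 3.31%. In those shared regions the fold over background was 15.9 ± 6.29 in MEF, 8.33 ± 0.480 in Stage 1, 5.91 ± 1.05 in Stage 2 and 4.47 ± 0.527 in iPSC (SD, n = 3 each), a ratio of 3.57 between MEF and iPSC. The sorted groups, which sorting alone would leave alike, also differed. Their shares of reads in regions were 7.64% in Stage 1, 6.03% in Stage 2 and 4.94% in iPSC, without overlap of the libraries. This argues against sorting as the cause of the fall from Stage 1 to iPSC. For MEF against the later groups, stronger enrichment in unsorted cells and a difference in the chromatin of the stages cannot be told apart. MEF alone were not sorted.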

How the results depend on the processing

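Whole-library scaling, equal depth, 1 gene per region, gene-end regions, background subtraction, the set of libraries with similar shares and all tests of lists among regions above both end points are tests chosen only after the data were seen. Named genes were not run with gene-end regions or 1 gene per region, so the effect of regions shared with other genes on them was not tested. Over the alternatives that were run, named genes kept direction and side of the threshold in 2282 cases, were no longer past it in 206, came past it in 16, turned in 8 and moved without a call in 16. Named regions did so in 320 and 27 cases for the first 2. Lists, by their camera direction relative to other genes, did so in 643 cases, with 44 lost, 11 gained, 15 moved and 1 turned. Those list cases hold the estimated correlation, the block, other links, left-out libraries and, in iPSC against Stage 2, equal depth and similar shares, but no other scaling. Whole-library scaling gave 9, 16, 11 and 12 of the 17 list medians the other sign in Stage 1 against MEF, Stage 2 against Stage 1, iPSC against Stage 2 and iPSC against MEF; cyclic loess did so for 3 in the third and 1 in the last, and library size only for 1 in the first and 1 in the last. Counts and values stayed within their limits in 341 cases and moved in 128. Where a result below changed, the cause was not tested, except that a fold threshold leaves fewer calls by construction. At these depths simulated 2-fold changes of regions were recovered in 31.3% to 44.8% of cases and of genes in 85.1% to 92.5%.

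DESeq2 covered 114998 regions where edgeR tested 71069, so the region counts of the 2 tools come from unlike sets. It called 1569 regions higher and 1774 lower in Stage 2 against Stage 1, and 52 and 642 in iPSC against Stage 2. Among genes it called 809 and 807, and 362 and 375. Regions in iPSC against Stage 2 were 215 higher without a filter, 1350 higher and 1467 lower with only the groups compared, and 632 lower with library size only and 467 with cyclic loess. Genes lower there were 965 with cyclic loess and 1072 with only the groups compared, and 625 were higher with 1 gene per region. Equal depth gave 16187 regions lower in Stage 1 and 17262 in iPSC, each against MEF. A log2 fold change of at least 1 left 2428 regions lower in Stage 2 against Stage 1 and 573 in iPSC against Stage 2; of genes it left 2378 higher and 1718 lower, 201 and 112, 67 and 26, and 2630 and 1193 in Stage 1 against MEF, Stage 2 against Stage 1, iPSC against Stage 2 and iPSC against MEF. Regions near gene ends gave 3711 genes higher and 3391 lower, 488 and 567, and 224 and 165 in the first 3 of these.

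Whole-library scaling gave 1100 regions higher in Stage 2 against Stage 1, 27 higher and 609 lower in iPSC against Stage 2 and 16839 higher in iPSC against MEF. Of genes it gave 1326 higher and 12233 lower in Stage 1 against MEF, 62 higher in Stage 2 against Stage 1, and 797 higher and 15174 lower in iPSC against MEF. In iPSC against Stage 2 edgeR then called 39 genes lower and 0 higher (63 higher and 3564 lower at an unadjusted p under 0.05; DESeq2 with its own scaling 362). It turned Klf4 (-0.87) and Myc (-0.91) in Stage 1 against MEF, and in iPSC against MEF Pou5f1 (-0.82), Klf4 (-1.43), Myc (-1.18), Nanog (-0.56), Cdh1 (-0.19) and Bmp4 (-0.12). With it the share of higher calls of regions was 37.4%, 19.7%, 4.25% and 29.1% in the 4 comparisons, against 49.8%, 47.8%, 26.9% and 47.6%, and of genes 9.78%, 4.88%, 0% and 4.99%, against 49.8%, 53.8%, 61.6% and 50.5%. In iPSC against Stage 2 the share for regions was 42.6% with library size only, 39.8% with cyclic loess and 7.49% with DESeq2.

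Regions beyond both end points were, in Stage 1, 7534 higher and 250 lower with whole-library scaling, 2559 lower with cyclic loess and 355 lower with DESeq2. In Stage 2 they were 352 higher and 196 lower with cyclic loess, 421 and 16 with DESeq2, 64 lower without a filter and 4 lower with whole-library scaling. The over-representation of 3 lists among regions higher than both end points kept its side of the threshold in 32 cases and lost it in 20; that of the pluripotency network in Stage 2 turned in 2, with an odds ratio of 0.731 with whole-library scaling and a range from 0 to 5.38 with each library left out. Lists past the threshold were 5, 0, 0 and 6 with an estimated correlation against 11, 3, 6 and 13, 6 in Stage 2 against Stage 1 with gene-end regions and 1 in iPSC against Stage 2 in libraries with similar shares. The endothelial list turned in iPSC against MEF with gene-end regions (median 1.28, camera adjusted p = 0.0119). The Stage 1 position was, over gained regions, 0.956 with library size only, 1.13 with whole-library scaling and 1.07 after background subtraction, and over lost regions 1.10, 0.913 and, with end points from held-out libraries, 1.20. The Stage 2 position was 1.13 and 1.10 over gained regions with the last 2 scalings, and 0.962 with whole-library scaling and 1.15 with held-out end points over lost regions. Positions of lost regions after background subtraction are left out because the measure saturates at 1. With at least 50% of both intervals shared, 76.2% of iPSC intervals overlapped Stage 2, 67.5% Stage 1 and 42.1% MEF.

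Leaving out each library gave these ranges for regions higher and lower: 28883 to 30409 and 27549 to 32525 in Stage 1 against MEF, 1890 to 2549 and 2147 to 3270 in Stage 2 against Stage 1, 62 to 183 and 160 to 681 in iPSC against Stage 2, and 28415 to 30214 and 29007 to 32592 in iPSC against MEF. For genes they were 5291 to 5790 and 4931 to 5624, 810 to 1270 and 824 to 1459, 453 to 662 and 275 to 539, and 5272 to 5631 and 5074 to 5838. Regions beyond both end points ranged from 3075 to 5211 higher and 762 to 1938 lower in Stage 1, and from 125 to 1169 and 18 to 194 in Stage 2; lists past the threshold from 9 to 11, 3 to 3, 4 to 7 and 12 to 13; and the Stage 1 position over lost regions from 1.04 to 1.09.

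Libraries with the same replicate number did not deviate together (r from -0.0645 to 0.0656 over 18 pairs). Replicates of the later stages differed by little more than sampling noise (chi-square per degree of freedom from 1.02 to 1.24). Such deviations could hardly correlate, so this does not exclude a pairing. With the replicate block edgeR called 3338 regions higher in Stage 2 against Stage 1 and 291 in iPSC against Stage 2, and no count moved by over 1.5 times. Not run were the planned motif shares with their alternatives, for which no genome sequence was used here, and the upper part of the interval lists by score, since the lists carry none.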

Other observations

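The tests chosen only after the result was seen are those on the most counted regions of the X chromosome, the comparison of libraries with similar shares and all splits of the libraries. The fold over background of the lists was also chosen then. Equal depth and background subtraction were not planned either, and were chosen after the data were seen. Measured against the background of each library, the pluripotency network was the one list of the 17 whose median was higher in Stage 1 than in MEF, at 6.44-fold against 3.54-fold. It was 5.35-fold in Stage 2 and 3.56-fold in iPSC, where all 34 genes stood above 2-fold. Over all genes the medians were 8.84-fold in MEF, 4.21-fold in Stage 1, 3.25-fold in Stage 2 and 2.49-fold in iPSC. Epithelial genes had 4.64-fold in MEF and 4.52-fold in Stage 1, and primed genes 5.54-fold and 4.37-fold. Mesenchymal genes had the lowest median of the lists after MEF, from 10.5-fold in MEF to 2.18-fold in Stage 1, with 26 of 47 genes above 2-fold there and 13 in iPSC. No test was made of these values.

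Of the lineage lists, definitive endoderm genes stood highest over background in iPSC at 3.23-fold, with 16 of 18 genes above 2-fold, then neural ectoderm genes at 2.68-fold with 20 of 26. TGF-beta pathway genes went from 10.4-fold in MEF to 1.87-fold in iPSC, with 11 of 25 above 2-fold, and endothelial markers from 6.13-fold to 2.29-fold, with 9 of 16. Markers of macrophages and other blood cells had 6.82-fold in MEF and 2.38-fold in iPSC, with 11 of 18 genes above 2-fold.

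From Stage 2 to iPSC the pluripotency list had a median log2 fold change of -0.26 and the mesenchymal list of 0.26, and a difference in the number of reads in regions is argued against by medians of -0.25 and 0.26 with libraries thinned to the same number (camera adjusted p = 2.49e-06 and 0.000143), which leaves total reads and the background share unmatched. After subtraction of background the pluripotency difference in list score was -0.11 (SE 0.0616) where it had been -0.18 (SE 0.0645; exact permutation p = 0.2 and 0.1), between the bounds set for background and against it, so background and the cells cannot be told apart with 3 libraries a group. The mesenchymal difference was 0.38 (SE 0.101) where it had been 0.26 (SE 0.0562; exact permutation p = 0.1 in both), past the bound set against background, but this bound was judged wrong after the value was seen: the list stood at 1.63-fold over background in both groups, where an even density can leave local background in, so the causes cannot be told apart there either. In Stage 2 replicate 3 against iPSC replicates 1 and 2, which had the closest shares of reads in regions, the medians were -0.15 and 0.16 (camera adjusted p = 0.0536 in both), which with a single Stage 2 library excludes nothing. A difference between the cells of the 2 groups stays open.

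The X chromosome share of reads in regions was lower in iPSC than in Stage 2 by a log2 ratio of -0.23, and a few regions with many reads are argued against by -0.24 without the top 1% of regions. For this test background was taken at the X and autosome read densities inside regions of the MEF list alone, not outside the regions. Such background is argued against as the whole cause by -0.17 after its subtraction, without overlap of the libraries, in regions of the Stage 2 or iPSC lists. The log2 ratio there was -0.20 before. The comparison that follows uses the same densities. A candidate explanation is fewer X copies per cell in iPSC, since in regions of the MEF list alone the ratio of X to autosome read density was lower by -0.20 on the log2 scale (0.560 ± 0.00984 against 0.644 ± 0.0311, SD, n = 3 each; exact permutation p = 0.1, the smallest possible). That ratio was also lower in each later group, from 0.769 in MEF and 0.685 in Stage 1, alongside the share of reads in regions, which this hypothesis leaves without account. The Y share also was lower in iPSC than in Stage 2, by -0.42 with overlap of the libraries (exact permutation p = 0.2), and higher than in MEF by 1.69, which fewer X copies do not account for; the sex of the animals is not in the labels, and a difference between the cells was not tested otherwise.

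Splits of 3 libraries against 3 number 10, too few for a share under 0.05, and each one but the real mixes the 2 groups, so that a difference between them widens the spread on each side. In edgeR fits of the 6 libraries compared, the real split was 1 of 10 with as many calls in each comparison. It gave 61080 regions for Stage 1 against MEF, 9053 for Stage 2 against Stage 1, 2817 for iPSC against Stage 2 and 58307 for iPSC against MEF, and 11004, 3063, 2281 and 11213 genes, with 0 as the highest other split each time. For lists past the threshold the real split gave 10 for Stage 1 against MEF (highest other 11), 3 for Stage 2 against Stage 1 (highest other 3), 7 for iPSC against Stage 2 (highest other 5) and 13 for iPSC against MEF (highest other 10), so 2, 2, 1 and 1 of 10 splits gave as many. For regions beyond both end points, 1 of 30 drawn splits of the 9 libraries, the real one, gave as many, with 3780 higher and 1671 lower in Stage 1, 681 higher and 95 lower in Stage 2, and 0 as the highest other. Of the other splits, 28 for each stage parted the MEF libraries, which are nearly uncorrelated with the later ones over the tested regions and so widen the spread within a group, and 1 kept them together, so neither these nor the splits of 6 libraries say anything on chance.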
